A study of Homo sapiens with 20 samples.

How the data were processed

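Bulk RNA sequencing of the hTERT-RPTEC cell line was analysed from the deposited gene tables. Cells were untreated or received TNFα, IFNγ or both, for 3 h or 12 h, in medium with 0.5 percent serum. Doses are not given in the sources used here, the labels give a single batch, and the protocol leaves open whether poly(A) selection or rRNA depletion was used. Per the labels, 20 libraries form 8 groups. The design was written for 20 libraries, but the count table covers 16 (2 per group), and 4 further libraries appear in the TPM table alone.

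The authors deposited estimated counts per gene, not scaled, and TPM values per gene. Per the submitters' processing notes featureCounts and Salmon were used with hg38; their versions, and which tool made which table, are not given in the sources used here. Of the positive count values, 9.03% (26322 of 291574) were fractional, and counts were rounded to whole numbers before testing. A stray header line in the TPM table (1 line) was dropped. The 8 columns with the same name in both tables correlated at 0.886 to 0.899. Ensembl identifiers were matched to symbols for 51996 genes (89.9%). Positions were taken from GENCODE release 29 for the genes it holds.

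Genes were filtered with filterByExpr (minimum count 10), scaled by TMM (factors 0.828 to 1.07) and tested with the edgeR quasi-likelihood F test, with 1 mean per group and 8 residual degrees of freedom. Tests were two-sided and adjusted by Benjamini-Hochberg, and called at an adjusted p below 0.05. The common biological coefficient of variation was 23.4%. The error given as ± is the SE, the absolute log2 fold change divided by the square root of F. Between 13184 and 14385 genes had at least 10 counts per library. Principal components used log CPM with a prior count of 2. The floor of 3 counts covers counting error only, while the SE also takes in the spread between libraries as estimated by the fit.

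The 16 comparisons were each treatment against the control of its time, both cytokines against each alone, the interactions, the differences of effects between 12 h and 3 h, and the controls over time. Before the data were examined, 38 gene lists were fixed, of which 35 had the minimum of 3 tested members. They were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, over 560 pairs. Members are also given as adjusted over the list alone. A gene was called separated where both treated libraries were at least 2-fold above (or below) both controls, at 5 CPM or more. Members at 0 in a group were set to a bound of 3 counts where stated. In the TPM table the untreated libraries and those with both cytokines carry replicate numbers, whose meaning the labels do not state. By the correlation of deviations from the group means, all 3 pairs with the same number were over 0.1 for both against control at 3 h (0.197 to 0.415) and for control over time (0.14 to 0.328), so the numbers were taken to pair these samples. Alternatives were a replicate block, DESeq2, RLE scaling, no filter, a term for the letter in the library name, the groups of a comparison alone, limma on log2(TPM + 1) for genes at 1 TPM or more in at least 2 libraries, and leaving out each library.

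Genes were named by a rule fixed beforehand: the 10 largest rises and 6 largest falls among called genes, up to 4 members passing and 2 not passing from each list described, and a set of cytokine, interferon, cell death and kidney genes. Other genes are said to be chosen after their values were seen. On simulated data with 50 genes planted per fold, edgeR recovered 15 at 2-fold and 40 at 4-fold in a 3 h comparison, and 8 and 33 in a 12 h comparison, with 6 and 5 false calls among 14479 genes. Outside the planted genes, the simulated means were the same in all libraries. Differences shared by many genes between the libraries of a group were not simulated. The numbers recovered therefore do not give the recovery in the real data. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.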

Results

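The RNA of hTERT-RPTEC, an immortalised human line of renal proximal tubule epithelial cells (the cells that reabsorb most of the filtered solutes in the kidney), was sequenced after 3 h or 12 h with TNFα, with IFNγ, with both cytokines or with neither. TNFα is an inflammatory cytokine that signals largely through NF-κB, and IFNγ is a cytokine of T and NK cells that signals through JAK kinases. The comparisons below ask which transcripts each cytokine altered at each time, what the second cytokine added, and how the effects differed between the times. Gene counts covered 16 libraries in 8 groups (n = 2 libraries per group), and TPM values covered 20. In each group of the count table, 1 library carries the letter a in its name and the other carries none. The latter is called the plain library here, and the labels do not say what the letter stands for. Library totals ran from 7992226 to 13063754 estimated counts, so that 3 counts, the level below which a value was not told from 0, were worth 0.226 to 0.408 CPM (counts scaled to the library total), which covers counting error only. After the filter on low counts, 14679 genes were tested. The labels do not say that the libraries of a group are separate cultures, so every p-value measures only the spread between these samples.

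The plain and the a libraries differed in ways the groups do not name. With a term for the letter in the edgeR fit, 626 genes differed between them (386 higher and 240 lower in the plain libraries). The term spans treated and untreated groups, so it also takes in responses that differed in size between the plain and the a libraries. Between the controls, plain minus a, interferon-list genes differed by a median log2 of -0.006 at both times. Cell cycle genes differed there by 0.408 at 3 h and 0.496 at 12 h. By camera at the preset correlation 15 of the 35 lists differed. Cell cycle genes were higher in the plain libraries by a median of 0.513 (camera adjusted p = 7.32e-37). The main fit holds no such term. Mitochondrially encoded transcripts took 0.540% to 5.27% of the counts in the plain libraries and 5.68% to 9.31% in the a libraries, and the lowest share was that of the plain TNFα 12 h library. That library also stood apart on the second principal component (score 81.2, 15.4% of the variance), and the plain TNFα+IFNγ 12 h library lay at the end of the first (score 97.5, 33.0% of the variance). For this reason the medians within the plain and within the a libraries are also given for part of the gene lists. A median given without them does not show whether the plain and the a libraries differed. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over all 560 pairs of a list and a comparison. Of these pairs 164 were called, 0 were called with an estimated correlation, and 61 of the 164 were called without any single library.

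Positions are those of GENCODE release 29 on GRCh38, matched by Ensembl identifier, and all of the genes placed here are annotated as protein coding. NFKBIA spans 35401511 to 35404749 on chromosome 14, TNFAIP3 137867188 to 137883312 on chromosome 6, ICAM1 10270835 to 10286615 on chromosome 19 and CCL2 34255218 to 34257203 on chromosome 17. IRF1 spans 132481609 to 132490798 on chromosome 5, GBP1 89052319 to 89065360 on chromosome 1 and IDO1 39902275 to 39928444 on chromosome 8. CXCL9 (76001275 to 76007488), CXCL10 (76021117 to 76023497) and CXCL11 (76033682 to 76041415) lie side by side on chromosome 4. HLA-DRA (32439842 to 32445046), TAP1 (32845209 to 32853978) and PSMB9 (32844136 to 32859585) lie in the MHC on chromosome 6, where the annotated spans of TAP1 and PSMB9 overlap. CLDN14, identified in the count table as ENSG00000159261.6, spans 36460621 to 36576569 on chromosome 21. Counts are per gene, so no value refers to a single exon or UTR. Values of near-identical family members (HLA, GBP, APOL, IFIT and the CXCL1 to CXCL3 genes), of overlapping genes such as TAP1 and PSMB9 and of genes with an antisense partner are uncertain, because the counting could divide their reads.

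After 3 h of TNFα, transcripts of the NF-κB pathway and its feedback rose. Of 29 tested, 28 were higher than in the untreated cells, with a median log2 fold change of 1.24 (1.00 in the plain and 1.30 in the a libraries). Of them, 18 passed when adjusted over the list alone against 0 over all genes (camera adjusted p = 6.07e-38; adjusted p = 0.569 with an estimated correlation). They included PTX3, a secreted pattern recognition protein (log2 fold change 3.95 ± 1.41, SE, n = 2), TNFAIP2 (3.32 ± 0.98), TNFAIP3, a deubiquitinase that restrains NF-κB (3.08 ± 1.13), the mitochondrial superoxide dismutase SOD2 (2.82 ± 0.89) and NFKBIA, the inhibitor of NF-κB (2.56 ± 0.66). TRAF3 (0.52 ± 0.26) and NFKBIZ (-0.16 ± 0.37) did not pass. Chemokine transcripts rose too, 9 of 12 being higher with a median of 1.97 (1.96 plain, 1.95 a; 2.22 with members at 0 set to their bound). Of them, 3 passed over the list alone and 0 over all genes (adjusted p = 4.78e-12; adjusted p = 0.569 with an estimated correlation). These were the neutrophil attractants CXCL3 (3.02 ± 0.91), CXCL6 (2.08 ± 0.67) and CXCL1 (1.82 ± 0.52). CXCL8 stood at 3.13 ± 1.21, the monocyte attractant CCL2 at 2.77 ± 1.08 and CXCL5 at 2.36 ± 1.24 without passing.

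Other lists moved less after 3 h of TNFα. Cytokines and growth factors rose (15 of 22 higher, median 0.84, 0 over the list alone and 0 over all genes, adjusted p = 0.000142; adjusted p = 0.569 with an estimated correlation), and the interleukin IL6 stood at 2.05 ± 0.56. IFNγ signalling and GAS targets, genes with gamma-activated sites, rose with 28 of 35 higher and a median of 0.43 (0.45 with members at 0 set to their bound). The receptor subunit IFNGR1 (0.86 ± 0.20) passed over the list alone, the 1 member to do so, against 0 over all genes (adjusted p = 5.86e-06; adjusted p = 0.81 with an estimated correlation). Pattern recognition receptors rose (12 of 16, median 0.37, 0 over the list alone, adjusted p = 0.00215; adjusted p = 0.569 with an estimated correlation). Cholesterol synthesis genes fell, with 20 of 24 lower and a median of -0.14 (0 over the list alone, adjusted p = 0.00127; adjusted p = 0.708 with an estimated correlation). The adhesion receptor ICAM1 was at 266 CPM in the plain and 574 CPM in the a TNFα library against 26.0 and 46.2 CPM in the controls (log2 fold change 3.54 ± 1.40, not passing over its lists).

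By edgeR over all genes, TNFα at 3 h gave 0 called genes and 374 at an unadjusted p under 0.05, where 734 would arise by chance. A number under that of chance shows that this fit, which takes its spread from all groups, was conservative here. With edgeR on the libraries of these groups alone, 1659 of 14059 tested genes were at an unadjusted p under 0.05. The 0 calls thus do not mean that no gene changed. DESeq2 called 7, limma on TPM called 2, edgeR without the filter 199 (162 higher and 37 lower), and edgeR on the libraries of these groups alone called 237 (201 higher and 36 lower), among them CCL2 (2.77 ± 0.13, adjusted p = 0.000303). In both TNFα libraries, 78 genes were at least 2-fold above both controls and 2 at least 2-fold below, against 5 for the highest other split; in TPM 35 were above. Chance separates 2 libraries from 2 others in a given direction for 16.7% of genes before any fold is asked. The 78 were chosen after their values were seen and held 13 of the 29 NF-κB and 8 of the 12 chemokine genes. Another 5 lists were called higher (programmed cell death, adhesion molecules, MHC class I, immune checkpoint ligands and extracellular matrix; medians 0.12 to 0.24), and each lost its call without the a TNFα 3 h library (adjusted p 0.0827, 0.0682, 0.0871, 0.112 and 0.413) and was not called with an estimated correlation (lowest adjusted p = 0.569).

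After 12 h of TNFα, the NF-κB and chemokine lists were still called, with a wide gap between the libraries. Of the 29 NF-κB genes, 26 were higher with a median of 0.88 (1.51 plain, 0.08 a), and 0 passed over the list alone or over all genes (adjusted p = 4.17e-09; adjusted p = 0.708 with an estimated correlation). The most abundant members were SOD2 at 1.42 ± 0.85 and TNFAIP2 at 1.73 ± 0.93. Chemokines were higher for 10 of 12 with a median of 1.69 (2.23 plain, 0.28 a), 0 over the list alone and 0 over all genes (adjusted p = 0.000326; adjusted p = 0.708 with an estimated correlation). CXCL5 stood at 2.18 ± 1.24 and CXCL14 at -0.03 ± 0.51. LTB, a TNF family cytokine chosen after its values were seen, was at 2184 CPM in the plain and 48.4 CPM in the a TNFα library against 9.77 and 46.0 CPM in the controls.

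Mitochondrially encoded transcripts fell after 12 h of TNFα, by a median of -0.84 with 12 of 13 lower (0 over the list alone and 0 over all genes, adjusted p = 8.38e-05; adjusted p = 0.767 with an estimated correlation). The median was -3.06 in the plain and -0.46 in the a libraries, beside the share of 0.540% in the plain TNFα library. MT-CO1, a subunit of cytochrome oxidase, was at 1695 CPM there and at 16310 CPM in the a library, against 8684 and 23820 CPM in the controls. Its list lost the call without the a control (camera adjusted p = 0.296) and turned in direction without the plain TNFα library. A further 5 lists were called higher (MHC class I, cytokines, p53 targets, extracellular matrix and immediate early genes; medians 0.13 to 0.47), and each lost its call without at least 1 library, with adjusted p up to 0.965, and was not called with an estimated correlation (lowest adjusted p = 0.569). Over all genes edgeR called 0 with 858 at an unadjusted p under 0.05, and 354 without the filter (310 higher and 44 lower). DESeq2, limma on TPM and edgeR on these groups alone called 0 each. Without the a TNFα 12 h library edgeR called 1760. Only 10 genes were at least 2-fold higher in both TNFα libraries than in both controls and 5 lower, against 46 for the split that put the a libraries on 1 side; in TPM 9 were higher, and 22 without the 12 h libraries numbered 3.

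After 3 h of IFNγ, transcripts of IFNγ signalling and GAS targets rose, 31 of 35 being higher with a median of 1.91 (2.29 plain, 0.40 a; 1.62 with members at 0 set to their bound). Over the list alone 3 passed and over all genes 0 (adjusted p = 1.64e-31; adjusted p = 0.569 with an estimated correlation), among them the apolipoprotein L gene APOL6 (2.72 ± 0.77) and the transcription factor IRF9 (1.91 ± 0.50). IRF1, another transcription factor, stood at 4.08 ± 1.36 and the GTPase gene GBP1 at 5.00 ± 1.71 without passing; GBP1 was at 886 and 57.5 CPM in the plain and the a library against 15.02 and 14.51 CPM in the controls. Type I interferon-stimulated antiviral genes rose with 46 of 47 higher and a median of 1.06 (1.66 plain, 0.18 a; 0 over the list alone and 0 over all genes, adjusted p = 8.99e-23; adjusted p = 0.657 with an estimated correlation). MHC class I antigen presentation genes rose with 20 of 21 higher and a median of 0.41 (0.62 plain, 0.14 a; 0 over the list alone and 0 over all genes, adjusted p = 8.99e-11; adjusted p = 0.708 with an estimated correlation). The abundant HLA-C stood at 0.22 ± 0.41 and B2M, the light chain, at 0.24 ± 0.40.

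The remaining 6 of the 9 lists called at 3 h of IFNγ each lost their call without at least 1 library and with an estimated correlation (lowest adjusted p = 0.569). Among them, programmed cell death (median 0.19), immune checkpoint ligands (0.45) and pattern recognition receptors (0.33) lost it without the plain IFNγ 3 h library (camera adjusted p = 0.293, 0.0894 and 0.0604). Cell cycle genes, lower by a median of -0.10, turned in direction without the plain control or the a IFNγ library. Gene by gene, edgeR called 0, with 133 at an unadjusted p under 0.05, and 152 without the filter (144 higher and 8 lower). DESeq2 called 0, limma on TPM 1 and edgeR on these groups alone 0. In both IFNγ libraries 20 genes (11 in TPM) were at least 2-fold above both controls and 2 below, against 16 for the highest other split, and 9 of the 20, chosen after their values were seen, belonged to the GAS list.

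After 12 h of IFNγ, genes of MHC class I antigen presentation, which load and display peptides for T cells, were higher for 21 of 21, with a median of 1.70 (2.00 plain, 1.15 a). Over the list alone 18 rose and over all genes 0 (adjusted p = 2.38e-40; adjusted p = 0.569 with an estimated correlation). They included the peptide transporter TAP1 (3.39 ± 1.12), the immunoproteasome subunits PSMB9 (3.21 ± 0.76) and PSMB10 (3.17 ± 0.73), HLA-F (3.15 ± 0.81) and B2M (1.40 ± 0.40). The chaperones CALR (0.39 ± 0.25) and CANX (0.15 ± 0.17) did not pass. Of the GAS targets, 32 of 35 were higher with a median of 2.86 (3.45 plain, 0.80 a; 2.87 with members at 0 set to their bound). Of them, 20 passed over the list alone and 0 over all genes (adjusted p = 2.35e-28; adjusted p = 0.569 with an estimated correlation). Examples were GBP4 (8.88 ± 2.60), the transcription factors ETV7 (6.63 ± 2.31) and BATF2 (6.06 ± 2.11), WARS1, a tryptophanyl-tRNA synthetase (5.06 ± 1.35), and APOL1 (2.86 ± 0.75). GBP5, whose controls were near 0, reached 698.5 CPM in the plain and 1.51 CPM in the a library, and STAT3 (0.05 ± 0.23) did not pass.

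Antiviral interferon-stimulated genes were higher for 47 of 47 after 12 h of IFNγ, with a median of 1.71 (2.24 plain, 0.75 a; 0 over the list alone and 0 over all genes, adjusted p = 2.38e-40; adjusted p = 0.569 with an estimated correlation). IFITM3 stood at 1.12 ± 0.49 and LGALS3BP at 0.89 ± 0.34. MHC class II genes were higher for 14 of 15 with a median of 2.77 (3.67 plain, 0.24 a; 2.63 with members at 0 set to their bound; 0 over the list alone and 0 over all genes, adjusted p = 1.63e-07; adjusted p = 0.601 with an estimated correlation). HLA-DRA was at 43.4 CPM in the plain and 0.226 CPM in the a library and at 0 in both controls, and the invariant chain CD74 at 493 and 21.6 CPM against 5.61 and 7.87 CPM. Among ubiquitin and proteasome genes (34 of 36 higher, median 0.27, adjusted p = 4.23e-15; adjusted p = 0.569 with an estimated correlation), 6 passed over the list alone and 0 over all genes, led by UBE2L6, the conjugating enzyme for ISG15 (3.02 ± 0.71), and UBA7, its activating enzyme (1.28 ± 0.24). Immune checkpoint ligands (11 of 13 higher, median 0.93, 4 over the list alone and 0 over all genes, adjusted p = 1.01e-07; adjusted p = 0.569 with an estimated correlation) included PDCD1LG2, a ligand of PD-1 (3.98 ± 1.19), and TNFRSF14 (3.55 ± 0.92), and CD274 stood at 3.67 ± 1.53. Complement genes were higher for 15 of 17 with a median of 0.81 (0 over the list alone, adjusted p = 1.06e-05; adjusted p = 0.576 with an estimated correlation), though C3 itself stood at 0.19 ± 1.11.

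Also called higher after 12 h of IFNγ were programmed cell death (median 0.32), glycolysis and hypoxia (0.26) and ribosomal protein genes (0.12), with camera adjusted p = 5.76e-05, 0.00038 and 0.000146; adjusted p = 0.708, 0.708 and 0.601 with an estimated correlation. Cell cycle, immediate early and pattern recognition genes lost their calls without at least 1 library (adjusted p up to 0.813, 0.91 and 0.359) and with an estimated correlation (adjusted p = 0.872, 0.782 and 0.708). Across all genes, edgeR called 0, with 479 at an unadjusted p under 0.05, 358 without the filter (328 higher and 30 lower) and 6, all higher, with a term for the letter. DESeq2 called 35 (34 higher and 1 lower), and limma on TPM and edgeR on these groups alone called 0. In both IFNγ libraries 81 genes were at least 2-fold above both controls and 5 below, against 14 for the highest other split; in TPM 3 were above, and 82 without the 12 h libraries numbered 3. Chosen after their values were seen, the 81 held 15 GAS, 12 antiviral, 10 MHC class I and 5 MHC class II genes.

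With both cytokines for 3 h, the NF-κB and the interferon lists rose side by side. GAS targets were higher for 34 of 35 with a median of 2.34 (3.00 plain, 1.17 a; 2.15 with members at 0 set to their bound). Of them, 17 passed over the list alone and 0 over all genes (adjusted p = 8.67e-33; adjusted p = 0.569 with an estimated correlation). They included ETV7 (7.54 ± 2.62), GBP4 (7.05 ± 2.36), BATF2 (5.78 ± 2.10), GBP1 (5.77 ± 1.77), ICAM1 (5.22 ± 1.51) and IRF1 (5.08 ± 1.42). NF-κB genes were higher for 28 of 29 with a median of 1.38 (1.54 plain, 1.21 a). Of them, 17 passed over the list alone and 0 over all genes (adjusted p = 1.19e-32; adjusted p = 0.569 with an estimated correlation), among them PTX3 (3.77 ± 1.41), TNFAIP3 (3.47 ± 1.15), SOD2 (3.33 ± 0.91) and NFKBIA (2.76 ± 0.67). Chemokines were higher for 11 of 12 with a median of 3.26 (3.62 plain, 1.84 a; 2.72 with members at 0 set to their bound), 7 over the list alone and 0 over all genes (adjusted p = 7.95e-15; adjusted p = 0.569 with an estimated correlation). In front were CXCL3 (3.62 ± 0.93), CCL2 (3.62 ± 1.12), CXCL2 (3.57 ± 1.22) and CXCL8 (3.50 ± 1.23). CXCL10, an attractant of activated T cells, was at 0 in both controls and at 3.69 CPM in the plain and 0 in the a library.

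Cytokines and growth factors went both ways within the list after 3 h of both cytokines (16 of 22 higher, median 1.16, adjusted p = 7.70e-06; adjusted p = 0.569 with an estimated correlation). Over the list alone 4 rose, namely TNF (3.42 ± 1.12), CSF1 (2.98 ± 0.81), IL6 (2.42 ± 0.57) and IL15 (1.76 ± 0.51), and TNFSF9 fell, against 0 over all genes. Antiviral genes (46 of 47 higher, median 1.26, 1.57 plain and 0.47 a, adjusted p = 1.95e-17; adjusted p = 0.708 with an estimated correlation) and MHC class I genes (21 of 21, median 0.76, adjusted p = 5.47e-11; adjusted p = 0.708 with an estimated correlation) had 0 members past the threshold over the list alone. Programmed cell death genes were higher for 31 of 37 with a median of 0.70 (0 over the list alone, adjusted p = 1.53e-09; adjusted p = 0.601 with an estimated correlation). The death receptor TNFRSF10B stood at 0.98 ± 0.32 and the survival gene MCL1 at 0.41 ± 0.33. Pattern recognition receptors (median 0.72), immune checkpoint ligands (0.92) and ubiquitin and proteasome genes (0.14) were called higher as well (camera adjusted p = 5.55e-07, 3.71e-05 and 0.000101; adjusted p = 0.569, 0.607 and 0.719 with an estimated correlation). Complement, adhesion, immediate early, extracellular matrix and tubular injury and repair genes were called higher but lost their calls without at least 1 library (adjusted p up to 0.685) and with an estimated correlation (lowest adjusted p = 0.569). Of the tubular injury and repair markers, 22 of 34 were higher with a median of 0.11 (0 over the list alone and 0 over all genes, adjusted p = 0.0136; adjusted p = 0.569 with an estimated correlation), and the call ended without the plain control (adjusted p = 0.0926) or the a treated library (adjusted p = 0.233). In the numbered TPM libraries a replicate block moved camera adjusted p across the threshold for these markers (0.0477 to 0.0515), immediate early genes (0.0421 to 0.0533) and extracellular matrix (0.0719 to 0.0316).

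CLDN14, a claudin of tight junctions, was the single gene called over all genes with both cytokines at 3 h (edgeR log2 fold change 2.70 ± 0.32, adjusted p = 0.0321, n = 2). Its levels were 47.0 and 36.1 CPM against 7.18 and 5.58 CPM in the controls. The fold stayed between 2.50 and 2.89 when a library was left out, while the adjusted p rose to 0.608 without the plain control, 1.00 without the a control, 0.436 without the plain and 0.111 without the a treated library. Beside this 1 call, edgeR gave 664 genes at an unadjusted p under 0.05, and 490 calls without the filter (383 higher and 107 lower). DESeq2 called 40 (31 higher and 9 lower), limma on TPM called 1 and edgeR on these groups alone called 108 (94 higher and 14 lower). In both treated libraries 138 genes were at least 2-fold above both controls and 17 below, against 20 for the highest other split; in TPM 84 were above. Chosen after their values were seen, the 138 held 16 GAS, 15 NF-κB, 12 antiviral and 7 chemokine genes. The 17 held SNAI1, a repressor of epithelial genes (5.93 and 4.90 CPM in the controls, 0.200 and 0.622 CPM with both cytokines), and NR3C2, the mineralocorticoid receptor (-1.70 ± 0.38).

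**Figure D1:**
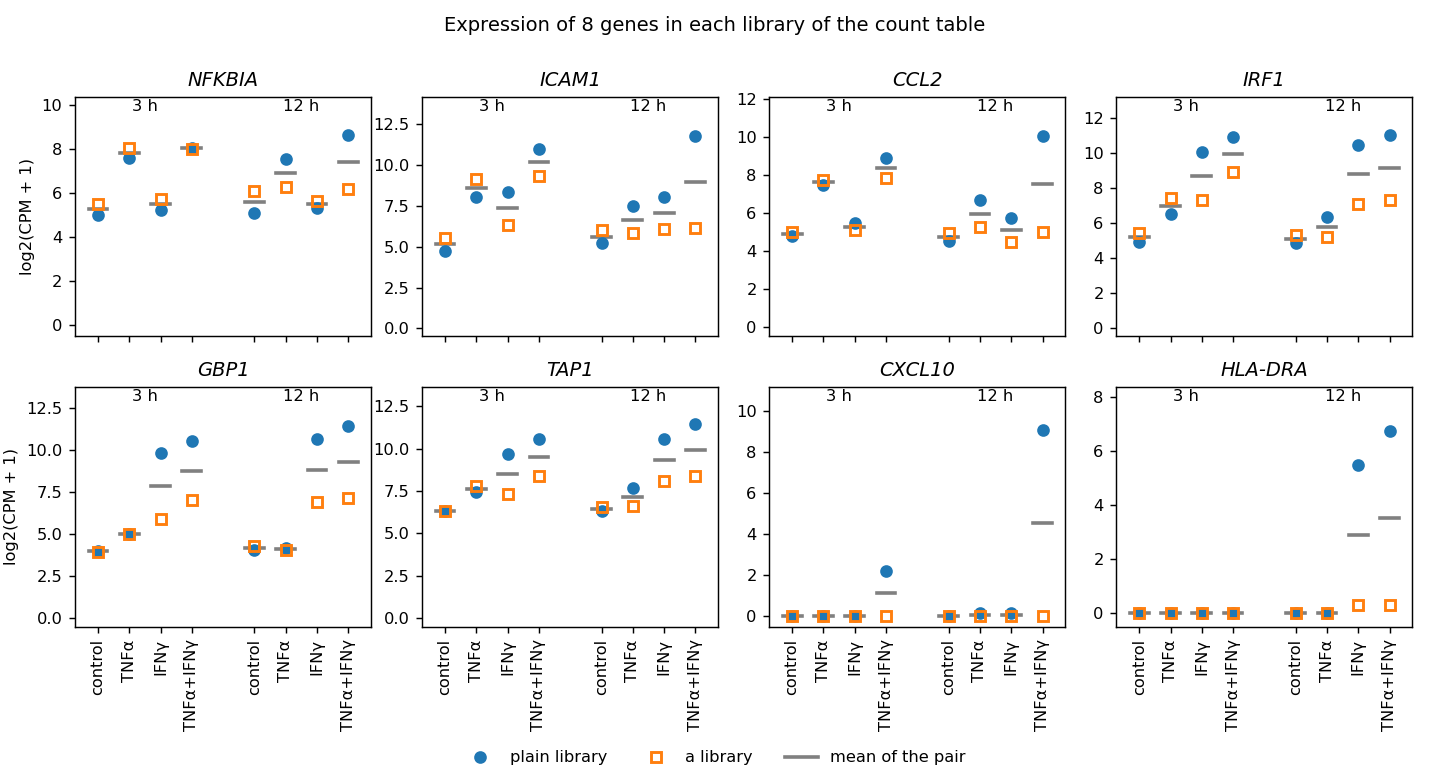
Expression of NFKBIA, ICAM1, CCL2, IRF1, GBP1, TAP1, CXCL10 and HLA-DRA in every library of the count table, as log2(CPM + 1), by treatment and time. Filled circles are the plain libraries, open squares the a libraries, and bars the mean of each pair. IRF1 with both cytokines at 12 h stood at 2047 CPM in the plain and 157 CPM in the a library.

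With both cytokines for 12 h, the called lists spanned antiviral defence, antigen presentation, chemokines, complement and cell death. Antiviral genes were higher for 47 of 47 with a median of 2.66 (3.30 plain, 0.78 a). Of them, 46 passed over the list alone and 0 over all genes (adjusted p = 2.12e-33; adjusted p = 0.569 with an estimated correlation). The widest gaps were those of RSAD2, OAS2 (9.67 ± 2.51) and CMPK2 (9.64 ± 2.85). RSAD2 was at 51.0 and 0.111 CPM in the plain and the a library. In the a library OAS2 rose by 1.79% and CMPK2 by 0.86% of their rises in the plain library. CMPK2 stood at 0.892 CPM in the a library, so these folds rest largely on the plain library. IFITM2 (0.35 ± 0.41) did not pass. MHC class I genes were higher for 21 of 21 with a median of 1.92 (2.47 plain, 1.32 a), 19 over the list alone and 0 over all genes (adjusted p = 5.61e-31; adjusted p = 0.569 with an estimated correlation). Among these were TAP1 (4.16 ± 1.16), HLA-F (4.08 ± 0.84), PSMB9 (3.40 ± 0.76) and B2M (1.90 ± 0.41). GAS targets were higher for 35 of 35 with a median of 3.45 (4.02 plain, 0.95 a), 30 over the list alone and 0 over all genes (adjusted p = 8.81e-24; adjusted p = 0.569 with an estimated correlation). Members included IRF1 (5.07 ± 1.43) and GBP4 (9.68 ± 2.66). Several members were near 0 outside the plain treated library: CXCL10 was at 534.5 CPM there and 0 in the a library and both controls, IDO1, which degrades tryptophan, at 477.5 CPM and 0, and the ubiquitin-like UBD at 2484 and 2.68 CPM.

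Chemokines were higher for 11 of 12 with both cytokines at 12 h, with a median of 3.68 (5.12 plain, 0.20 a). Of them, 11 passed over the list alone and 0 over all genes (adjusted p = 1.15e-07; adjusted p = 0.569 with an estimated correlation). CXCL2 (4.88 ± 1.28), CXCL5 (4.83 ± 1.38), CCL2 (4.42 ± 1.16) and CXCL8 (3.50 ± 1.23) were among them. CXCL11 stood at 634 and 0 CPM in the plain and the a library, CXCL9 at 97.2 and 0 CPM, and CCL5 at 265.8 and 0 CPM, the latter both below the filter of the test. NF-κB genes were higher for 26 of 29 with a median of 1.44 (2.10 plain, 0.13 a), 17 over the list alone and 0 over all genes (adjusted p = 3.99e-14; adjusted p = 0.607 with an estimated correlation). The largest folds were those of TRAF1 (5.13 ± 1.32), TNFAIP3 (3.69 ± 1.16) and SOD2 (3.40 ± 0.92). MHC class II genes were higher for 15 of 15 with a median of 4.61 (5.22 plain, 0.40 a; 4.22 with members at 0 set to their bound), 7 over the list alone and 0 over all genes (adjusted p = 1.09e-06; adjusted p = 0.651 with an estimated correlation). Those passing included CD74 (6.80 ± 1.66), HLA-DPA1 (5.73 ± 1.83) and the protease CTSS (4.61 ± 1.11). Complement genes went both ways, 12 of 17 being higher with a median of 3.30 (4.38 plain, 0.65 a). Of them, 8 passed over the list alone and 0 over all genes (adjusted p = 1.19e-05; adjusted p = 0.58 with an estimated correlation), with C1R (5.22 ± 1.20), SERPING1 (5.21 ± 1.62) and C3 (4.47 ± 1.27). C3 was at 4958 and 126 CPM.

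Programmed cell death genes were higher for 34 of 37 with both cytokines at 12 h, with a median of 0.69 (1.22 plain, 0.14 a). Of them, 14 passed over the list alone and 0 over all genes (adjusted p = 1.87e-11; adjusted p = 0.569 with an estimated correlation). They included the death ligand TNFSF10 (2.94 ± 0.81), BBC3 (2.61 ± 0.74), the inflammatory caspase CASP1 (2.56 ± 0.80), the necroptosis effector MLKL (2.36 ± 0.67) and the death receptor FAS (1.37 ± 0.43). GSDMD stood at 0.58 ± 0.30, CASP8 at 0.84 ± 0.38 and RIPK3 at 0.33 ± 0.95. Immune checkpoint ligands (12 of 13 higher, median 2.54, 8 over the list alone and 0 over all genes, adjusted p = 8.50e-08; adjusted p = 0.569 with an estimated correlation) included CD274, which encodes PD-L1 (4.71 ± 1.57), PDCD1LG2 (4.36 ± 1.20) and TNFRSF14 (3.84 ± 0.93). Ubiquitin and proteasome genes (34 of 36, median 0.36, 11 over the list alone and 0 over all genes, adjusted p = 1.55e-12; adjusted p = 0.569 with an estimated correlation) included ISG15 (3.94 ± 1.15). Pattern recognition receptors (15 of 16, median 0.92, 6 over the list alone and 0 over all genes, adjusted p = 4.01e-06; adjusted p = 0.569 with an estimated correlation) included TLR2 (2.63 ± 0.67), TLR4 (2.14 ± 0.56) and STING1 (1.82 ± 0.55). Of cytokines and growth factors 16 of 22 were higher (median 1.12, 9 over the list alone and 0 over all genes, adjusted p = 1.65e-05; adjusted p = 0.569 with an estimated correlation), among them TNFSF13B (5.57 ± 1.77) and IL32 (5.34 ± 1.36). The markers of other nephron segments were the 1 list that fell, with 7 of 8 lower and a median of -1.03 (0 over the list alone, adjusted p = 0.00362; adjusted p = 0.58 with an estimated correlation), TFCP2L1 standing at -1.08 ± 0.54. The call ended without the plain control (adjusted p = 0.156).

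Another 5 lists called higher with both cytokines at 12 h (glycolysis and hypoxia, immediate early genes, ribosomal proteins, ER stress and cholesterol synthesis; medians 0.14 to 0.50) each lost their call without at least 1 library, with adjusted p up to 0.918, and with an estimated correlation (lowest adjusted p = 0.708). With edgeR, 0 genes were called, with 1550 at an unadjusted p under 0.05 where 734 would arise by chance. Without the filter edgeR called 1018 (787 higher and 231 lower), and with a term for the letter 24 (23 higher and 1 lower). DESeq2 called 175 (172 higher and 3 lower), limma on TPM 0 and edgeR on these groups alone 0. Without the a library with both cytokines edgeR called 1853. In both treated libraries 113 genes were at least 2-fold above both controls and 4 below, against 18 for the highest other split; in TPM 2 were above, and 112 without the 12 h libraries numbered 3. Chosen after their values were seen, the 113 held 19 GAS, 14 antiviral, 11 MHC class I, 6 MHC class II and 5 complement genes but 1 NF-κB and 1 chemokine gene.

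What IFNγ added to TNFα was read from both cytokines against TNFα alone. At 3 h GAS targets rose, 33 of 35 being higher with a median of 1.91 (2.60 plain, 0.52 a; 1.68 with members at 0 set to their bound), 0 over the list alone and 0 over all genes (adjusted p = 8.05e-24; adjusted p = 0.569 with an estimated correlation). WARS1 stood at 2.56 ± 1.21. Antiviral (median 0.92), MHC class I (0.36) and ubiquitin and proteasome genes (0.11) were called without any single library as well (adjusted p = 1.35e-15, 5.73e-07 and 1.76e-05 by camera; adjusted p = 0.708, 0.719 and 0.708 with an estimated correlation). A further 6 lists lost their calls without at least 1 library, with adjusted p up to 0.936, and with an estimated correlation (lowest adjusted p = 0.678). In the test of all genes edgeR called 0 with 265 at an unadjusted p under 0.05, and 162 without the filter (148 higher and 14 lower). DESeq2 called 2, limma on TPM 1 and edgeR on these groups alone 0. In both libraries 18 genes were at least 2-fold higher than with TNFα alone and 2 lower, against 10 for the highest other split, and 11 of the 18, chosen after their values were seen, were GAS targets.

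At 12 h both cytokines against TNFα alone gave higher antiviral genes for 47 of 47, with a median of 2.52 (3.32 plain, 0.63 a). Of them, 42 passed over the list alone and 0 over all genes (adjusted p = 3.84e-33; adjusted p = 0.569 with an estimated correlation). IFI27 (9.45 ± 1.81), OAS2 (8.14 ± 2.24), CMPK2 (7.70 ± 2.43) and RSAD2 (7.59 ± 2.38) had the largest folds. Against control, OAS2, CMPK2 and RSAD2 rose in the a library by 1.79%, 0.86% and 0.219% of their rises in the plain library. GAS targets (34 of 35 higher, median 2.99, 29 over the list alone and 0 over all genes, adjusted p = 2.58e-21; adjusted p = 0.58 with an estimated correlation) rose too. So did MHC class I genes (21 of 21, median 1.56, 18 over the list alone, adjusted p = 5.16e-19; adjusted p = 0.569 with an estimated correlation) and ubiquitin and proteasome genes (34 of 36, median 0.46, 18 over the list alone, adjusted p = 9.84e-13; adjusted p = 0.569 with an estimated correlation). B2M was 1.62 ± 0.41 higher and APOL1 2.82 ± 0.75. MHC class II genes (median 3.88, 3.16 with members at 0 set to their bound) and complement genes (median 2.58) lost their calls without the plain library with both cytokines (adjusted p = 0.218 and 0.0707 by camera; adjusted p = 0.69 and 0.607 with an estimated correlation). The chemokine and NF-κB calls (medians 2.15 and 0.35; adjusted p = 0.791 and 0.94 with an estimated correlation) turned in direction without it. Mitochondrially encoded transcripts were called higher (median 0.61, 3.74 plain and -0.25 a, adjusted p = 0.00111; adjusted p = 0.81 with an estimated correlation) beside the share of 0.540% in the plain TNFα library, and turned without that library. For single genes, edgeR called 0 with 1847 at an unadjusted p under 0.05, 1017 without the filter (695 higher and 322 lower) and 8, all higher, with a term for the letter. DESeq2 called 70 (58 higher and 12 lower), limma on TPM 0 and edgeR on these groups alone 0. Without the a library with both cytokines edgeR called 1502 and without the a TNFα library 1380. At least 2-fold higher in both libraries were 70 genes and lower 6, fewer than the 129 of the highest other split, which put the a libraries on 1 side; in TPM 25 were higher, and 77 without the 12 h libraries numbered 3.

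What TNFα added to IFNγ was read from both cytokines against IFNγ alone. At 3 h NF-κB genes rose, 28 of 29 being higher with a median of 1.25 (1.24 plain, 1.12 a). Of them, 13 passed over the list alone and 0 over all genes (adjusted p = 1.51e-36; adjusted p = 0.569 with an estimated correlation), among them TNFAIP3 (3.28 ± 1.14), TNFAIP2 (2.98 ± 0.97), the apoptosis inhibitor BIRC3 (2.72 ± 0.85) and NFKBIA (2.54 ± 0.66). Chemokines rose with 11 of 12 higher and a median of 2.75 (3.17 plain, 1.63 a; 2.55 with members at 0 set to their bound), 5 over the list alone and 0 over all genes (adjusted p = 7.63e-19; adjusted p = 0.569 with an estimated correlation). These included CXCL8 (3.67 ± 1.25), CCL2 (3.19 ± 1.10), CXCL3 (3.18 ± 0.91) and CXCL1 (1.94 ± 0.52). Cytokines and growth factors were higher by a median of 0.73 and cholesterol synthesis genes lower by a median of -0.11 (adjusted p = 7.60e-05 and 0.00397 by camera; adjusted p = 0.569 and 0.708 with an estimated correlation). Another 5 lists lost their calls without at least 1 library, with adjusted p up to 0.987, and with an estimated correlation (lowest adjusted p = 0.569). Tested 1 by 1, 0 genes were called by edgeR with 363 at an unadjusted p under 0.05, and 185 without the filter (150 higher and 35 lower). DESeq2 called 7, limma on TPM 3 and edgeR on these groups alone 0. In both libraries 56 genes were at least 2-fold higher and 9 lower, fewer than the 104 of the split that put the plain libraries on 1 side.

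At 12 h both cytokines against IFNγ alone gave NF-κB genes higher for 29 of 29, with a median of 1.02 (1.50 plain, 0.22 a). Of them, 16 passed over the list alone and 0 over all genes (adjusted p = 8.66e-26; adjusted p = 0.569 with an estimated correlation), with TNFRSF9 (4.76 ± 1.62), TRAF1 (4.36 ± 1.23), TNFAIP3 (3.86 ± 1.17) and NFKBIA (2.40 ± 0.66). This was the 1 list of 16 called here that was called without any single library. Chemokines (median 3.68, 4.56 plain and 0.26 a, 11 of 12 over the list alone and 0 over all genes, adjusted p = 3.02e-12; adjusted p = 0.569 with an estimated correlation) and cytokines (median 0.75, 3 over the list alone and 0 over all genes, adjusted p = 1.41e-05; adjusted p = 0.569 with an estimated correlation) lost their calls without the plain library with both cytokines (adjusted p = 0.462 and 0.654). CXCL5 was 4.38 ± 1.35 higher, IL6 2.28 ± 0.57 and TNF 3.74 ± 1.13. The antiviral, GAS, MHC class I and MHC class II calls (medians 0.71, 0.51, 0.23 and 1.38; adjusted p = 0.933, 0.93, 0.966 and 0.891 with an estimated correlation) turned in direction without the same library, with adjusted p of 1.02e-21, 8.94e-10, 1.38e-06 and 4.85e-06 the other way. Among all genes tested, edgeR called 0 with 598 at an unadjusted p under 0.05, and 376 without the filter (334 higher and 42 lower). DESeq2 called 6, limma on TPM 0 and edgeR on these groups alone 0. Without the a library with both cytokines edgeR called 624. At least 2-fold higher in both libraries were 10 genes and lower 2, against 231 for the split that put the plain libraries on 1 side.

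The interaction asked whether the effect of both cytokines differed from the sum, on the log2 scale, of the effects of each. At 3 h 0 lists were called (lowest adjusted p = 0.783 with an estimated correlation), and edgeR called 0 genes with 91 at an unadjusted p under 0.05, as did DESeq2 (0) and edgeR on these groups alone (0), while limma on TPM called 1 and edgeR without the filter 11 (6 above and 5 below the sum). With a term for the letter, camera called 2 lists at the preset correlation and 0 with an estimated correlation. At 12 h 7 lists were called, each lost without at least 3 single libraries and with an estimated correlation (lowest adjusted p = 0.569). Antiviral genes were above the sum by a median of 0.66 (0.75 plain, -0.02 a, adjusted p = 0.00699; adjusted p = 0.974 with an estimated correlation) and NF-κB genes by 0.36 (adjusted p = 0.0077; adjusted p = 0.933 with an estimated correlation). Both turned in direction without the plain library with both cytokines (adjusted p = 1.54e-09 and 0.000186). Cell cycle genes were below the sum by a median of -0.43 (adjusted p = 0.00102; adjusted p = 0.935 with an estimated correlation) and turned without the plain TNFα library (adjusted p = 0.0138). CCL2 stood at 2.51 ± 1.46. By the edgeR test 0 genes were called with 343 at an unadjusted p under 0.05, and 107 without the filter (61 above and 46 below the sum). DESeq2, limma on TPM and edgeR on these groups alone called 0 each. Without the a TNFα library edgeR called 377 and without the a library with both cytokines 5.

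Effects at 12 h minus those at 3 h were tested directly. For IFNγ, MHC class I genes gained with 20 of 21 higher and a median difference of 1.02 (1.19 plain, 0.69 a, 0 over the list alone and 0 over all genes, adjusted p = 3.06e-17; adjusted p = 0.569 with an estimated correlation), B2M standing at 1.16 ± 0.56. Ubiquitin and proteasome genes gained by a median of 0.23 (adjusted p = 8.27e-07; adjusted p = 0.708 with an estimated correlation). These 2 of the 10 lists called were called without any single library. For both cytokines MHC class I genes gained by a median of 1.15 (1.39 plain, 0.62 a, adjusted p = 1.94e-14; adjusted p = 0.607 with an estimated correlation) and cholesterol synthesis genes by 0.32 (adjusted p = 4.60e-06; adjusted p = 0.569 with an estimated correlation), again 2 of the 12 lists called that were called without any single library. For TNFα the NF-κB effect was smaller at 12 h by a median of -0.42 (0.19 plain, -1.15 a, adjusted p = 0.000535; adjusted p = 0.852 with an estimated correlation), a call that ended without the a TNFα 12 h library (adjusted p = 0.979), and 0 of its 6 lists kept the call through every omission. Gene by gene edgeR called 0 for the 3 differences, with 249 (TNFα), 110 (IFNγ) and 228 (both) at an unadjusted p under 0.05, and 51, 81 and 135 without the filter. DESeq2 called 1, 1 and 0, limma on TPM 0, 1 and 0, and edgeR on the groups alone 0 each. Without the a TNFα 12 h library the TNFα difference gave 210, and leaving out single libraries gave up to 4 for both cytokines.

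The untreated cells at 12 h were compared with those at 3 h as a background for time in culture. The p53 targets rose with 16 of 21 higher and a median of 0.26 (0.26 plain, 0.31 a; 0 over the list alone and 0 over all genes, adjusted p = 0.000117; adjusted p = 0.569 with an estimated correlation). The abundant members PLK2 and CCNG1 stood at -0.09 ± 0.18 and 0.32 ± 0.19. Cholesterol synthesis genes fell with 20 of 24 lower and a median of -0.24 (adjusted p = 7.18e-06; adjusted p = 0.569 with an estimated correlation). Nuclear oxidative phosphorylation subunits fell with 56 of 72 lower and a median of -0.11 (adjusted p = 0.00276; adjusted p = 0.656 with an estimated correlation). Both calls ended without the a control at 12 h (adjusted p = 0.0877 and 0.102). GBP1 stood at 0.23 ± 1.52 and NFKBIA at 0.38 ± 0.63 in the count table, while the TPM table also holds a library labelled control 12 h replicate 3 with GBP1 at 1210 TPM. Of all genes edgeR called 0 with 427 at an unadjusted p under 0.05, 41 without the filter (18 higher and 23 lower) and 1 with a term for the letter. DESeq2 called 2, and limma on TPM and edgeR on these groups alone called 0.

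Several lists showed no called change in any of the 16 comparisons. The call concerns the shift of a list as a whole, so single members could still rise or fall. Proximal tubule transport and identity genes had medians between -0.15 and 0.14 (lowest adjusted p = 0.065 with camera), with the endocytic receptor gene CUBN at -0.63 ± 0.42 and the water channel AQP1 at -2.45 ± 0.89 after 12 h of both cytokines. Gluconeogenesis (lowest adjusted p = 0.688), NRF2 and oxidative stress genes (0.215), ferroptosis and iron genes (0.0715), enzymes of tryptophan and nitric oxide metabolism (0.329), replication-dependent histones (0.208) and fibroblast and pericyte markers (0.346) were likewise not called. These results cover tested members only: 38 of 64 for proximal tubule, 9 of 14 for gluconeogenesis, 7 of 33 for histones and 4 of 13 for fibroblast and pericyte markers. The proximal tubule genes LRP2 and HNF4A were below the filter of the test. The tryptophan and nitric oxide list includes IDO1 and WARS1, whose rises are given above. Of its 11 tested members, 2 were at least 2-fold above both controls in both libraries after 12 h of IFNγ. After 12 h of both cytokines, 2 were so as well. The leukocyte and endothelial markers had too few tested members for a test. The tubular injury and repair markers were called in 1 comparison, that of both cytokines at 3 h, but not with an estimated correlation (adjusted p = 0.569) nor without the plain control or the a treated library (adjusted p = 0.0926 and 0.233). Of these markers, HAVCR1 (KIM-1) stood at -0.52 ± 0.45 after 12 h of both cytokines and LCN2 (NGAL) was between 0 and 1.36 CPM in every library.

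**Figure D2:**
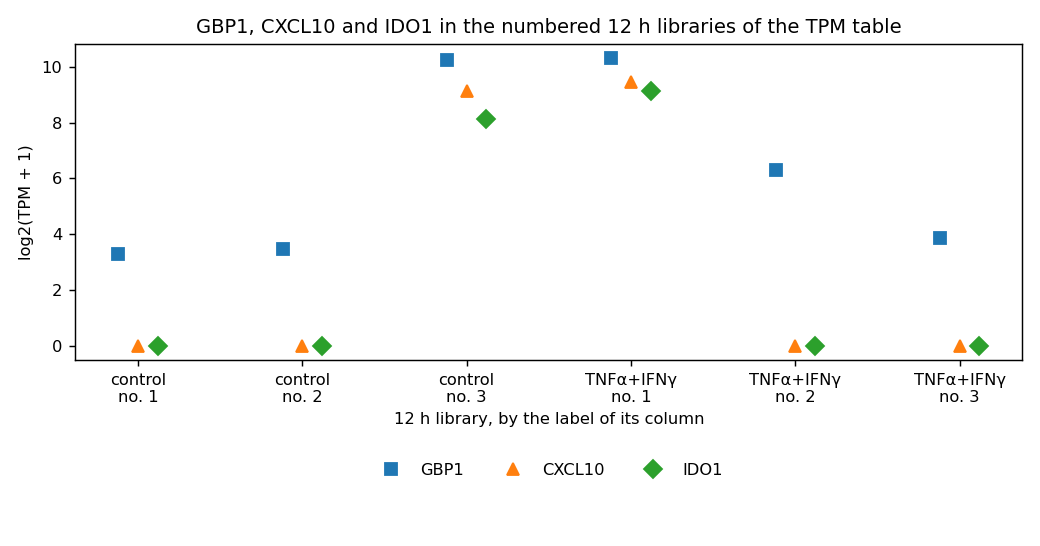
Levels of GBP1, CXCL10 and IDO1, as log2(TPM + 1), in the numbered 12 h libraries of the TPM table, by the label of the column. GBP1 was at 1210 TPM in the library labelled control replicate 3 and at 13.6 TPM in that labelled as both cytokines, replicate 3.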

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

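The tests of the 3 patterns weighed here were chosen after the result was seen. Differences between the effects at 12 h and at 3 h brought the gene lists below to this part, by a test of the difference itself, as median log2 differences. With an estimated correlation 0 of them were called; 0 of 6 (TNFα), 2 of 10 (IFNγ) and 2 of 12 (both) kept the call when each library was left out in turn, and 1, 2 and 6 turned in direction. For TNFα they were mitochondrially encoded transcripts (-1.15), NF-κB (-0.423), cholesterol synthesis (0.26), GAS targets (-0.367), cell cycle (0.243) and nuclear oxidative phosphorylation (0.147). For IFNγ they were MHC class I (1.02), antiviral genes (0.869), cell cycle (0.462), ubiquitin and proteasome (0.228), MHC class II (2.05), complement (0.519), glycolysis and hypoxia (0.214), ribosomal proteins (0.0787), GAS targets (0.628) and checkpoint ligands (0.497). For both cytokines they were MHC class I (1.15), antiviral genes (1.38), cholesterol synthesis (0.319), ubiquitin and proteasome (0.195), glycolysis and hypoxia (0.35), MHC class II (2.96), complement (1.51), checkpoint ligands (0.509), ER stress (0.358), epithelial junctions (-0.152), cell cycle (0.154) and programmed cell death (0.298).

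The interferon responses and the 12 h responses were weaker in the a libraries than in the plain ones. Lower sequencing depth is argued against by the ratio of totals, a over plain, of 0.991, and at 3 h a weakening common to TNFα and IFNγ by the NF-κB response to TNFα, whose median in the a libraries minus that in the plain ones was -0.0334; at 12 h, where it was -1.43, a common weakening stays open. Untreated RNA mixed into the a library of both cytokines at 12 h is argued against by 8 interferon-list genes at under 1 of 5 parts of the predicted CPM; for IFNγ at 12 h, with 2 such genes, mixing cannot be told apart. A different culture or library batch stays open, since the untreated plain and a libraries already differed in cell cycle genes (0.408). No biological explanation was tested.

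Data outside the count table held transcripts of the GAS list at high levels in an untreated group: the library labelled control 12 h replicate 3 had 1210 TPM of GBP1, 565 of CXCL10 and 281 of IDO1. An exchange of labels with the library labelled as both cytokines, replicate 3, stays open, as that library lay at the level of controls 1 and 2 over GAS genes (0.124), though treated replicate 2 was low too (0.907, with CXCL10 and IDO1 at 0) and controls 1 and 2 grouped with treated replicate 3, as an exchange predicts, called 23 genes by limma against 504 with treated replicate 2. A small carry-over is argued against by a median of 96.8% of the rise of treated replicate 1. An exchange at treatment or at harvest cannot be told apart from one of labels, since both give the same values (3.46 for the library labelled control). No biological explanation was tested.

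The plain TNFα 12 h library stood apart by its low mitochondrial share. GC content bias as the whole cause is argued against, since mitochondrial transcripts lay lower than nuclear genes of the same GC range by a log2 of -3.57. A fall with TNFα whether or not IFNγ is present cannot be told apart, since with both cytokines the plain library lay above its control (0.683) and the a library below (-0.711). A fall with TNFα alone and a fault of this library both stay open, untested.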

How the results depend on the processing

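The main edgeR tests, the filter, RLE scaling, DESeq2, the groups alone, limma on TPM, the replicate block, genes with 1 library left out and the estimated correlation were set before the data were examined. The chance splits of the groups with 3 libraries were set with the data at hand but before their result was seen. Chosen after seeing the data were the letter term, TPM without the 12 h libraries numbered 3, the numbered libraries without a block, the splits by pairs, the list tests on TPM (but for the replicate block) and with 1 library left out, and the separated genes with all their settings. The main tests were planned on 20 libraries and run on the 16 with counts. Counts of called genes follow the order TNFα, IFNγ and both against control, each at 3 h then 12 h, then both against TNFα, both against IFNγ, the interactions, the differences over time for TNFα, IFNγ and both, and control over time. Without the filter they were 199, 354, 152, 358, 490, 1018, 162, 1017, 185, 376, 11, 107, 51, 81, 135 and 41. DESeq2 gave 7 (TNFα 3 h), 35 (IFNγ 12 h), 40 and 175 (both, 3 h and 12 h), 2 and 70 (both against TNFα), 7 and 6 (both against IFNγ), and 1, 1 and 2 for TNFα, IFNγ and control over time. The groups alone gave 237 (TNFα 3 h) and 108 (both, 3 h). The letter term gave 6 (IFNγ 12 h), 24 (both, 12 h), 8 (both against TNFα, 12 h) and 1 (control over time). Limma on TPM gave 2 (TNFα 3 h), 1 (IFNγ 3 h), 1 (both against TNFα, 3 h), 3 (both against IFNγ, 3 h), 1 (interaction, 3 h) and 1 (IFNγ over time); without the 12 h libraries numbered 3 it gave 2, 1, 1, 3, 1 and 2, with 2 for both at 3 h and 1 for both against IFNγ at 12 h. RLE scaling left every count of called genes as it was, moved the called lists from 164 to 161, and moved the separated genes from 10 to 11 (TNFα 12 h) and from 81 to 80 (IFNγ 12 h). The cause was not tested in any of these.

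With 1 library left out, the lone sample of an arm is assumed to vary like the other groups. Counts then ran from 0 to 1760 (TNFα 12 h), 0 to 1 (IFNγ 12 h), 0 to 0 (both, 3 h), 0 to 1853 (both, 12 h), 0 to 1502 and 0 to 624 (both against TNFα and IFNγ, 12 h), 0 to 377 (interaction, 12 h), 0 to 210 and 0 to 4 (TNFα and both over time) and 0 to 1 (control over time). With an estimated correlation 0 lists were called, and 0 with the letter term added. At the preset correlation the letter term gave 181 called pairs of a list and a comparison, against 164 without it. Genes separated in TPM of all libraries were 35 and 9 (TNFα, 3 h and 12 h), 11 and 3 (IFNγ), 84 and 2 (both) and 25 (both against TNFα, 12 h). Without the 12 h libraries numbered 3 they were 35 and 22 (TNFα), 11 and 82 (IFNγ), 84 and 112 (both) and 77 (both against TNFα, 12 h).

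Some lists turned in direction, with adjusted p by camera. On TPM these were GAS targets (0.000809) and antiviral genes (0.038) for IFNγ over time, and antiviral genes (3.70e-08), programmed cell death (1.04e-06) and complement (0.0143) for both over time. Without the 12 h libraries numbered 3 none of these turned: GAS (0.0492) and antiviral genes (1.65e-06) for IFNγ and antiviral genes (2.55e-08) for both were called in the direction of the count table, while cell death (0.638) and complement (0.0842) were not called. Leaving out 1 library gave 1.69e-10 to 0.905 (NF-κB) and 3.47e-20 to 0.367 (chemokines) for both against TNFα at 12 h. Against IFNγ at 12 h it gave 3.65e-14 to 0.497 (GAS), 1.02e-21 to 0.201 (antiviral), 1.10e-10 to 0.132 (MHC class I), 8.70e-08 to 0.902 (MHC class II), 0.000426 to 0.861 (complement) and 0.000121 to 0.846 (checkpoint). For the interaction at 12 h it gave 2.07e-15 to 0.284 (antiviral), 1.61e-13 to 0.952 (NF-κB) and 8.65e-11 to 0.95 (cell cycle). Over time it gave 1.81e-08 to 0.92 (TNFα, cell cycle), 1.13e-10 to 0.682 (IFNγ, GAS), 2.01e-29 to 0.0447 (both, antiviral) and 6.41e-07 to 0.417 (both, cell death). Why leaving out a library moved these was not tested.

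For both against control at 12 h, 1 of 3 pairs with the same number correlated over 0.1 (-0.401 to 0.425), so these values alone do not show that the number pairs them. The pair numbered 3 (-0.272) holds the libraries whose labels are in doubt. Over all groups 15 of 18 pairs were over 0.1. All 3 were for control at 12 h with both at 3 h (0.124 to 0.296) and for both at 3 h with both at 12 h (0.186 to 0.192). The columns of TNFα alone, IFNγ alone and the count table carry no replicate numbers, so no replicate block was fitted there; the letter term was. In the numbered TPM libraries the replicate block called 1 gene for both at 3 h and 0 elsewhere, as did the fit without the block. By camera it moved antiviral (0.0292 to 0.0703), NF-κB (0.0285 to 0.0515) and cholesterol synthesis genes (0.0664 to 0.0261) across the threshold for both at 12 h and ribosomal proteins (0.14 to 0.0475) for control over time, and changed no other call but the 3 given in the report for both at 3 h. For both over time antiviral, cell death and complement genes turned without the block (4.28e-08, 8.09e-07 and 0.0119) as with it (4.42e-07, 1.65e-06 and 0.02). These fits include the 12 h libraries numbered 3.

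Limma on TPM of 3 libraries against 3 allows 10 splits, too few for a share under 0.05: both against control at 3 h called 1 gene (3 splits as large, highest other 1), control over time 0 (10 splits, highest other 1) and both at 12 h 0 (10 splits, highest other 504). That split put controls 1 and 2 with treated replicate 2, which points to a structure of the samples. Where 0 genes were called every split is as large by construction, so the splits decide nothing for control over time, both at 12 h or both over time (0 called, 100 of 100 splits, highest other 19). Of the 4 splits parting all 3 pairs, 2 called 1 gene for both at 3 h, the real one included, and control over time gave a highest other of 1; the other 6 part 1 pair.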

Other observations

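FOXD1, a transcription factor chosen after its values were seen, differed between the plain and the a libraries of some groups. At 3 h its plain and a libraries held 0.287 and 25.1 CPM (control), 0.448 and 24.3 CPM (IFNγ), 1.83 and 2.41 CPM (TNFα) and 22.7 and 0.249 CPM (both). At 12 h they held 27.4 and 0.123 CPM (control), 31.4 and 30.7 CPM (IFNγ), 3.25 and 3.30 CPM (TNFα) and 2.45 and 1.90 CPM (both).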
